A study of Mus musculus with 7 samples.

How the data were processed

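Hypothalamus RNA from 7 male Bgn knockout mice was measured on Illumina bead arrays with biotin-labelled targets, per the labels' protocols. The labels place 2 samples in the untreated group, replicates 1 and 3, and 5 samples in the DHA diet group, replicates 1 to 5. The series text counts 3 untreated mice and 5 mice on the diet and states that 1 untreated sample was left out as an outlier. Each sample therefore appears to be a separate mouse, although no label names the animal, and if samples were not separate animals the p-values would cover only the spread between these samples.

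Per the file headers, the unnormalized table the authors deposited holds a signal intensity and a detection p-value for each probe and array. From the values, the intensity is linear and no background had been subtracted, since the lowest signals lay between 117 and 124. The detection p-value compares a probe with the negative controls of its array. The table also holds 2 per-sample columns, a signal and its detection p-value, that match no sample of the series and were not used. A table of the authors' normalized values was deposited as well. Compared with the unnormalized signals of the same arrays, it is on the linear intensity scale, and its column for DHA replicate 5 equals the unnormalized signals of that array, with a largest difference of 0. Its array medians were 174.7 and 174.9 in the untreated replicates 1 and 3, and 175.01, 174.8, 174.9, 174.5 and 174.5 in the DHA replicates 1 to 5. The submitters' processing notes name lumi 2.10.0 and R 2.15.0; which of its normalizations was applied, the scanner software and the slide layout are not given in the sources used here. The normalized table served as an alternative, because it cannot show what was done between scanner and table.

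All values were computed from the unnormalized table with R 4.3.3 and limma 3.58.1. Background was corrected by normexp with parameters from the detection p-values and an offset of 16, followed by quantile normalization and log2. This order sets all arrays to a common distribution, so differences in total RNA per array are removed, and the offset shrinks the fold changes of dim probes. Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 1719 had none and 0 had several; 23962 had a gene identifier found in the mouse gene table of GRCm38.p6, which was used only to update the names. No genome build is named by the files, and no coordinates are given. Probes with a detection p under 0.05 in at least 2 arrays were tested, which left 15284 probes for 10448 named genes and 879 probes without a name. A probe detected in no array of a group has only a bound there. Its fold is given as at least N-fold, the mean of the brighter group over a mean of, per array, the higher of the lowest detected signal and the probe's own signal.

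The diet groups were compared per probe with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Log2 fold changes are DHA minus untreated, with the standard error of the fit. Array similarity was described by Pearson correlation and principal components. A total of 32 gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, on the brightest probe of each gene. They cover hypothalamic neuropeptides, feeding receptors, lipid and energy metabolism, matrix, inflammation, stress, housekeeping groups, brain cell types, neighbouring brain regions, meninges, choroid plexus, pituitary and blood. The same lists were tested with the correlation estimated per list, with fry, and with an exact permutation test of the list score (the mean log2 signal of its members) over the 21 splits of the 7 arrays into 2 and 5. Fry asks whether the genes of a list move one way on balance, or in its mixed form whether they change in either direction; it compares the list with no other genes.

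The groups, the main tests, the gene lists, the rule for naming genes and all but 3 alternatives were chosen before the data were examined. The 3 alternatives added later are the permutation test of list scores, the lists without genes shared with the meninges list, and a liver transcript score as a covariate. By the naming rule the text gives Bgn; up to 10 probes per direction, taken by fold change among those past the threshold and otherwise by smallest p among probes whose groups do not overlap, passing over unnamed, predicted and clone-named genes; up to 4 members of each called list with the smallest p in its direction; and fixed genes, of which 23 passed the filter. The brightest probe stands for a gene with several probes, and disagreeing probes are named. The alternatives tried were the deposited values, no background correction, normexp on the signals with an offset of 50, scaling to a common median, no detection filter, detection p under 0.01 in all 7 arrays, an intensity trend with robust variances, array weights, the replicate number as a block, the mean of all probes per gene, other thresholds and leaving out each array in turn. A block for slides was not run, because no slide is given.

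The test was tested on simulated data with the probes' own means and with variances drawn around the moderated ones of the fit, over 15284 probes. Of 50 probes changed at each size, 26% of those changed 1.5-fold, 72% at 2-fold, 92% at 3-fold and 92% at 4-fold were recovered, with 6 false calls. In the same way camera recovered a simulated shift of 0.5 log2 in 1 list and called 0 others, with genes drawn independently. In the data the correlation estimated per list lay above the preset 0.01 for every list that camera called. It ran from 0.019 for astrocytes to 0.62 for meninges and fibroblasts. The simulation therefore does not show how often camera calls lists falsely in these data. Nor do the recovered shares give the power for single probes in these data. Recovery depends on how many probes change and on their variances. In the data Ogn, which differed by 2.58 log2, did not pass (limma adjusted p 0.168). The figures were drawn with Python 3.11.15 and matplotlib 3.10.9.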

Results

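Gene expression was measured in the hypothalamus, the brain region that governs feeding, body temperature and pituitary hormone release, of 13-week-old male mice labelled as Bgn knockouts on a C57BL/6 background. Bgn encodes biglycan, a small leucine-rich proteoglycan of the extracellular matrix. The untreated group held 2 arrays (replicates 1 and 3). The diet group held 5 arrays from knockout mice fed for about 6 weeks a chow with 0.5% flaxseed oil and 1.2% oil from capsules of docosahexaenoic acid (DHA), the main omega-3 fatty acid of brain membranes. Of 25697 probes per array, 13970 and 13873 were detected in the untreated replicates 1 and 3. The DHA arrays detected 14251 to 14534. The median unnormalized signal was 167.4 and 173.2 in the untreated arrays and between 174.5 and 189.5 in the DHA arrays, so every DHA array was brighter and detected more probes than both untreated arrays. The small number of arrays limits the precision of every comparison.

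All 7 mice carried the Bgn knockout label. The single Bgn probe (ILMN_2964042) was nevertheless detected in all 7 arrays, with a detection p of 0 and a mean log2 signal of 8.30 ± 0.21 (SD, n = 7). Its log2 signal was 8.70 and 8.39 in the untreated arrays and 8.02 to 8.30 in the DHA arrays. The difference of -0.34 (SE 0.12) had a limma adjusted p of 0.417. Whether the probe lies within the deleted part of the gene is not given in the sources used here, so its signal does not check the genotype.

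The arrays were close to one another over the 15284 tested probes. Pearson's r across probes was 0.991 for the untreated pair, 0.988 ± 0.00189 (SD, 10 pairs) among the DHA arrays and 0.986 ± 0.00156 (SD, 10 pairs) between the diets. These differences are of the size of the spread between pairs. The first 3 principal components held 26.7%, 20.5% and 15.5% of the variance, and on each of the first 2 both untreated arrays lay outside the range of the DHA arrays.

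The design asks how hypothalamic gene expression differs between untreated Bgn knockout mice and those fed the chow with both oils. No group was fed flaxseed oil alone or a matched oil, so DHA cannot be told apart from flaxseed oil or added oil. Below, "with DHA" means this diet. At the preset correlation, upward shifts were called for genes of the meninges and fibroblasts and of the extracellular matrix, with median fold changes of 2.65 and 1.35, and for vascular, immune, glucocorticoid-responsive, stress and astrocyte lists. Downward shifts were called for oxidative phosphorylation and for striatal neuron genes, the latter carried by 1 untreated array. With an estimated correlation 0 of the 32 lists passed. The lists of hypothalamic neuropeptides and of long-chain fatty acid synthesis and transport did not pass camera. The neuropeptides passed a test for changes in either direction (fry in limma, adjusted p 0.00233), which compares the list with no other genes. No single probe passed the test.

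In limma, 0 of 15284 probes had an adjusted p under 0.05, and the smallest was 0.0963. At an unadjusted p under 0.05 there were 1565 probes, 790 higher and 775 lower with DHA, where chance alone gives 764.2. Of these, 75 were at least 2-fold higher and 6 at least 2-fold lower. The groups did not overlap for 2591 probes, or 17% (chance gives 9.52%). On the authors' normalized values, 12 probes passed (11 higher, 1 lower), and with an intensity trend and robust variances 52 passed (46 higher, 6 lower). Without untreated replicate 3, 3 probes passed, those of Parp2, Apex1 and 1700123O20Rik, which are named here after their values were seen.

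The probes with the smallest p among those higher with DHA are given as values that did not pass. Tagln (ILMN_1243652), which encodes the smooth muscle actin-binding protein transgelin, and the secreted ligand Wnt6 (ILMN_2901765) were detected in all 5 DHA arrays and in neither untreated array. They were at least 1.47-fold and at least 1.79-fold higher. Rapgefl1 differed by 2.07 log2 (SE 0.23), although its other probe differed by -0.03. Aoc3, an amine oxidase of vessel walls detected in 1 of 2 untreated arrays, differed by 1.42 (SE 0.17), and Itih2, a hyaluronan-binding protein, by 1.35 (SE 0.17). The endothelial receptor Gpr182 differed by 1.07 (SE 0.14) on a probe detected in all 7 arrays and by 1.45 (SE 0.21) on a probe detected in 1 of 2 untreated arrays. The transforming growth factor receptor Tgfbr2 differed by 0.72 (SE 0.09), the endocytic adaptor Dab2 by 0.86 (SE 0.11), and the complement inhibitor Serping1 by 1.54 (SE 0.21). The limma adjusted p of these 10 probes lay between 0.0963 and 0.118.

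Among the probes lower with DHA, other probes of the same gene mostly differed less. Trim9, a ubiquitin ligase of neurons, differed by -0.88 (SE 0.10), against -0.17 and -0.23 on its other probes. Pomt1, a protein O-mannosyltransferase, differed by -0.69 (SE 0.09), against -0.24. Tnip2, an inhibitor of NF-kappaB signalling detected in 3 of 5 DHA arrays, differed by -0.94 (SE 0.12), against -0.17. Anapc15 of the anaphase-promoting complex differed by -0.76 (SE 0.10), Champ1, which acts in chromosome alignment, by -0.54 (SE 0.08), and Mok, a kinase, by -0.89 (SE 0.14), against -0.16. Mfsd3 differed by -0.55 (SE 0.08), against -0.18 and 0.20. Foxred1, an assembly factor of respiratory complex I, differed by -0.67 (SE 0.11), with other probes between -1.02 and 0.12. Banf1, a chromatin-binding protein of the nuclear envelope, differed by -0.70 (SE 0.11), against -0.07 to -0.24. Iqcf3 was detected in both untreated arrays and in 0 of 5 DHA arrays, and was at least 1.13-fold lower. The limma adjusted p of these 10 probes also lay between 0.0963 and 0.118.

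**Figure D1:**
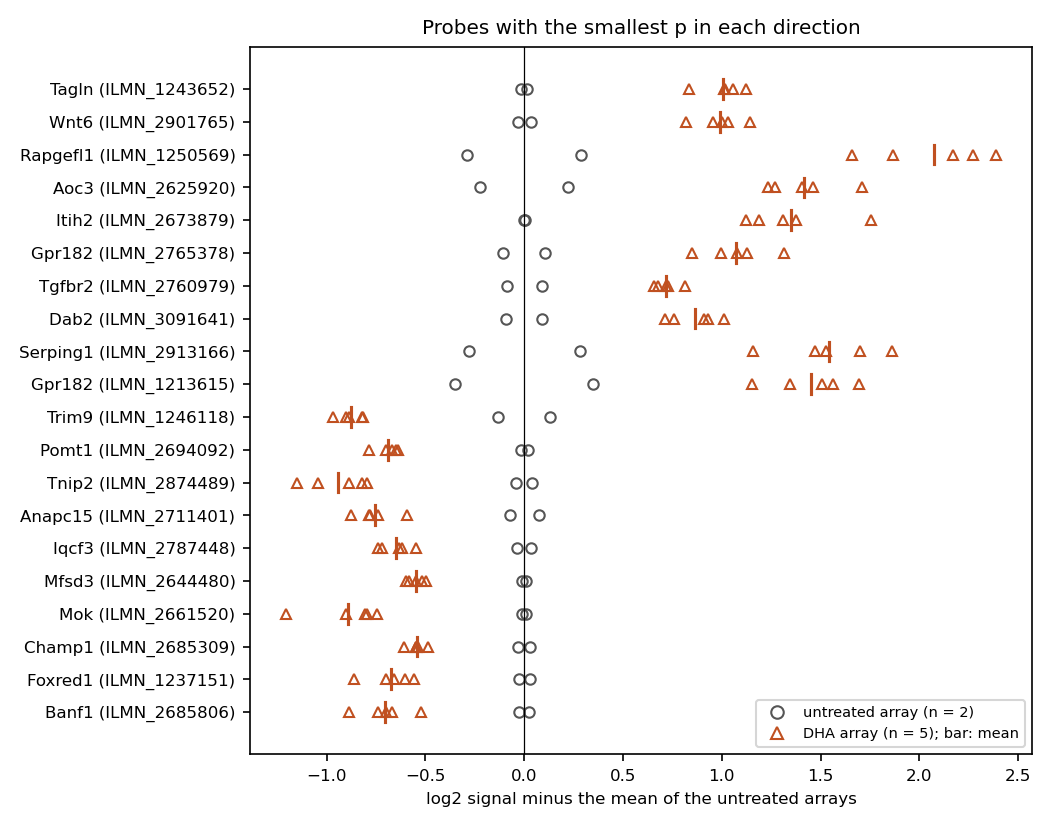
Log2 signal of each array minus the mean of the untreated arrays (horizontal axis) for the 10 probes with the smallest p in each direction; circles are the 2 untreated arrays, triangles the 5 DHA arrays and bars the DHA mean. For Rapgefl1 the DHA mean lay 2.07 above the untreated mean and for Trim9 it lay at -0.88, and no probe shown has overlapping groups.

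Of the 32 gene lists, 9 passed camera at an adjusted p under 0.05, 7 upward and 2 downward. With an estimated correlation 0 of the 32 passed (2 at an unadjusted p under 0.05), and the directional test of fry also passed 0. In the exact permutation test of list scores, 7 lists reached an unadjusted p of 0.0476, the smallest that 21 splits allow. Their adjusted p was 0.218, and since nearly all 32 lists would have to reach that smallest p for any to pass, the 0 lists past 0.05 there say nothing for or against the calls. The mixed test of fry, which takes changes in either direction, passed 9 lists, of which 5 are among those called by camera (meninges, matrix, endothelium, glucocorticoid-responsive genes and oxidative phosphorylation). The other 4 were hypothalamic neuropeptides, perineuronal net proteoglycans (both with a fry mixed adjusted p of 0.00233), ribosomal proteins (0.011) and choroid plexus (0.0362). No member of any list passed when adjusted over all probes tested.

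**Figure D2:**
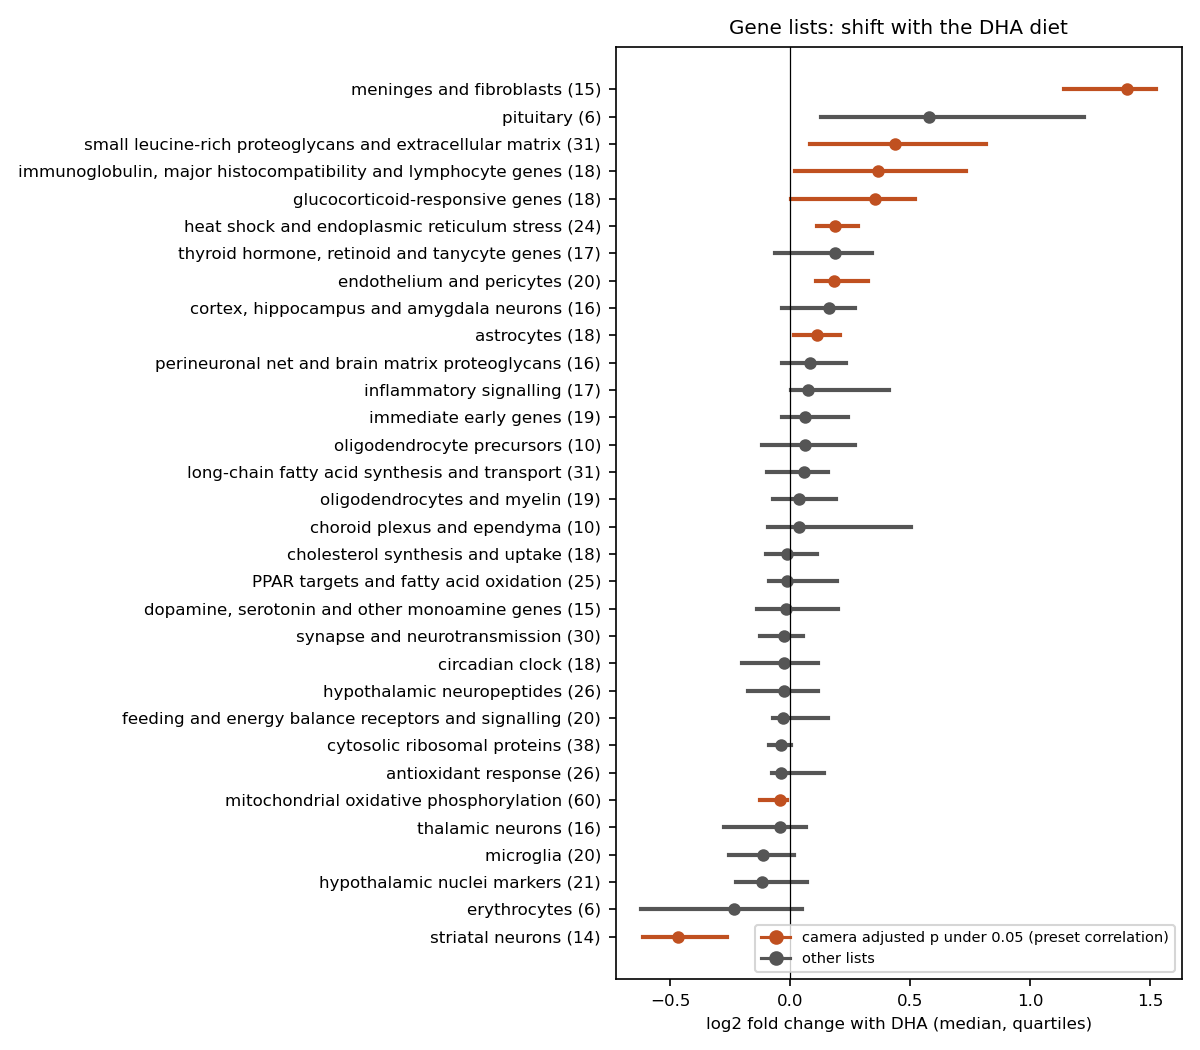
Median (points) and quartiles (lines) of the log2 fold change, DHA over untreated, over the members of each of the 32 gene lists, with the number of tested members in brackets. Orange marks the 9 lists with a camera adjusted p under 0.05 at the preset correlation; the meninges and fibroblast list has the highest median, 1.41, and the striatal list the lowest, -0.47.

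The meninges and fibroblast list rose. All 15 tested members were higher with DHA, the median was 1.41 log2 and the camera adjusted p was 6.76e-18, against an adjusted p = 0.354 with an estimated correlation. The list score was 8.31 and 7.53 in the untreated replicates 1 and 3 and lay between 8.79 and 9.54 in the DHA arrays. When adjusted over the list alone, 13 members passed. The examples by the naming rule were Serping1, the forkhead factor Foxc1 of meningeal cells (0.99, SE 0.15), the cation exporter Slc47a1 (1.40, SE 0.25) and the proteoglycan osteoglycin, Ogn (2.58, SE 0.48). Of the other probes of Slc47a1, 1 differed by 0.64 and 2 were detected in neither untreated array. Of these 2, 1 was at least 1.13-fold higher (limma adjusted p 0.533) and the other is given no fold. Igf2, the growth factor secreted by meninges and choroid plexus (1.55, SE 0.33), and the prostaglandin D synthase Ptgds (1.09, SE 0.22) are named after their values were seen. The collagen Col1a1 (0.43, SE 0.35) and Islr (0.31, SE 0.20) were the members that did not pass over the list alone.

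The list of small leucine-rich proteoglycans and extracellular matrix also rose, and 27 of its 31 members were higher. Its median was 0.44 and its camera adjusted p 1.52e-09, against an adjusted p = 0.354 with an estimated correlation. When adjusted over the list alone, 14 members passed upward and 1 downward, Bgn itself. The matrix glycoprotein fibulin 1, Fbln1, differed by 1.09 (SE 0.16), decorin, Dcn, by 1.31 (SE 0.25), and the calcification inhibitor Mgp by 1.497 (SE 0.32), with Ogn as above. Fibromodulin, Fmod, was detected in 1 of 2 untreated arrays and differed by 1.73 (SE 0.44), and its other probe, detected in neither untreated array, was at least 1.37-fold higher (limma adjusted p 0.349). The list shares 5 tested members with the meninges list. Without them its median was 0.37 over 26 genes (camera adjusted p 2.57e-06). Those 26 still include Fmod, Tgfbi, Prelp and Omd, which also stand on a separate list of meningeal transcripts described below. The shift of the remaining genes is therefore not free of meningeal genes. On the authors' normalized values, where background had not been subtracted, and without background correction, the median of the full list was 0.22.

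Genes of endothelium and pericytes rose by a smaller amount, beside the rise of the meninges list. The median was 0.18 with 18 of 20 members higher (camera adjusted p 0.000202), and the adjusted p = 0.354 with an estimated correlation. When adjusted over the list alone, 2 members passed. Apart from Tagln, the named members were the pericyte-enriched matrix protein vitronectin, Vtn (0.87, SE 0.18), smooth muscle actin, Acta2 (1.34, SE 0.39), and the glucose transporter of the blood-brain barrier, Slc2a1 (0.30, SE 0.12). Without untreated replicate 3 the median was 0.10 and no longer passed (camera adjusted p 0.121), without untreated replicate 1 it was 0.29, and on the authors' normalized values and without background correction it was 0.08.

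The list of immunoglobulin, major histocompatibility and lymphocyte genes rose, again beside the meninges list, with 15 of 18 members higher and a median of 0.37 (camera adjusted p 0.0014). The adjusted p = 0.429 with an estimated correlation, and 0 members passed when adjusted over the list alone. The groups overlapped in the list score. It was 6.30 and 6.03 in the untreated replicates 1 and 3, 6.20 in DHA replicate 1 and up to 6.80 in the other DHA arrays. Cd163, a haemoglobin scavenger receptor of perivascular macrophages, was detected in neither untreated array and was at least 1.25-fold higher. The mannose receptor Mrc1 differed by 0.97 (SE 0.31), the class II invariant chain Cd74 by 0.99 (SE 0.34) and the class II gene H2-Ab1 by 1.02 (SE 0.36). With its 5 members that were undetected in one group held at their bounds, the median was 0.02. Without untreated replicate 3 the list no longer passed (median 0.27, camera adjusted p 0.0632). The median was 0.61 without untreated replicate 1, 0.58 without DHA replicate 1, and 0.13 both on the authors' normalized values and without background correction. It was 0.19 with normexp and an offset of 50, 0.14 without the detection filter and 0.71 over probes detected in all arrays. The microglia list had a median of -0.11 with 15 of 20 members lower and did not pass (camera adjusted p 0.247).

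Glucocorticoid-responsive genes rose, with 13 of 18 members higher and a median of 0.35 (camera adjusted p 0.0014), against an adjusted p = 0.354 with an estimated correlation. Adjusted over the list alone, 1 member passed, the sulfotransferase Sult1a1, which differed by 0.74 (SE 0.12). Pdk4, which restrains pyruvate oxidation, differed by 0.65 (SE 0.19), the xanthine dehydrogenase Xdh, detected in 1 of 2 untreated arrays, by 0.86 (SE 0.28), and the lipid droplet protein Plin4 by 1.004 (SE 0.35). On the authors' normalized values and without background correction the median was 0.21.

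Heat shock and endoplasmic reticulum stress genes rose slightly, with 21 of 24 members higher and a median of 0.19 (camera adjusted p 0.000492). The adjusted p = 0.429 with an estimated correlation, and 0 members passed when adjusted over the list alone. The co-chaperone Bag3 differed by 0.28 (SE 0.11), the disulfide isomerase Pdia3 by 0.24 (SE 0.09), the small heat shock protein Hspb1 by 0.81 (SE 0.35) and Creld2 by 0.39 (SE 0.18). Without untreated replicate 1 the median was 0.09 and the list did not pass (camera adjusted p 0.0611), and without untreated replicate 3 it was 0.29.

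Astrocyte genes rose least, with 14 of 18 members higher and a median of 0.11 (camera adjusted p 0.0316), against an adjusted p = 0.354 with an estimated correlation. No member passed over the list alone (0 of 18). The calcium-binding protein S100b differed by 0.36 (SE 0.10), the folate enzyme Aldh1l1 by 0.30 (SE 0.13; other probes 0.04 and -0.08), angiotensinogen, Agt, by 0.21 (SE 0.11) and the filament protein Gfap by 0.28 (SE 0.19). A further probe of Aldh1l1, detected in neither untreated array, was at least 1.04-fold higher (limma adjusted p 0.566). The list no longer passed without untreated replicate 1 (median 0.05, camera adjusted p 0.358), without DHA replicate 3 (0.10, adjusted p 0.0566) or without DHA replicate 5 (0.11, adjusted p 0.0656). It also did not pass with arrays scaled to a common median (0.04, adjusted p 0.125).

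Striatal neuron genes fell. All 14 members were lower, the median was -0.47 and the camera adjusted p 0.000655, against an adjusted p = 0.429 with an estimated correlation. When adjusted over the list alone, 0 members passed. The signalling regulator Rgs9 differed by -0.57 (SE 0.16), the actin cross-linker Actn2 by -0.51 (SE 0.21), the G protein subunit Gng7 by -0.54 (SE 0.27) and the dopamine receptor Drd2 by -0.40 (SE 0.21). One array carried this shift. The list score was 9.35 in untreated replicate 1, 8.40 in untreated replicate 3 and 8.28 to 8.59 in the DHA arrays. Without untreated replicate 1 the median turned to 0.02 (camera adjusted p 0.939), and without untreated replicate 3 it was -0.83.

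Genes of mitochondrial oxidative phosphorylation fell by a very small amount, with 51 of 60 members lower and a median of -0.04 (camera adjusted p 0.00696). The adjusted p = 0.354 with an estimated correlation, and 0 members passed when adjusted over the list alone. The complex III subunit Uqcrfs1 differed by -0.40 (SE 0.16) on a probe detected in 1 of 2 untreated and 2 of 5 DHA arrays. The complex I subunits Ndufs6, Ndufv1 and Ndufb3 differed by -0.20, -0.18 and -0.19 (SE 0.08, 0.08 and 0.09). With arrays scaled to a common median the list median was -0.15. With the replicate number as a block it was -0.058, and the list did not pass (camera adjusted p 0.0749).

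**Figure D3:**
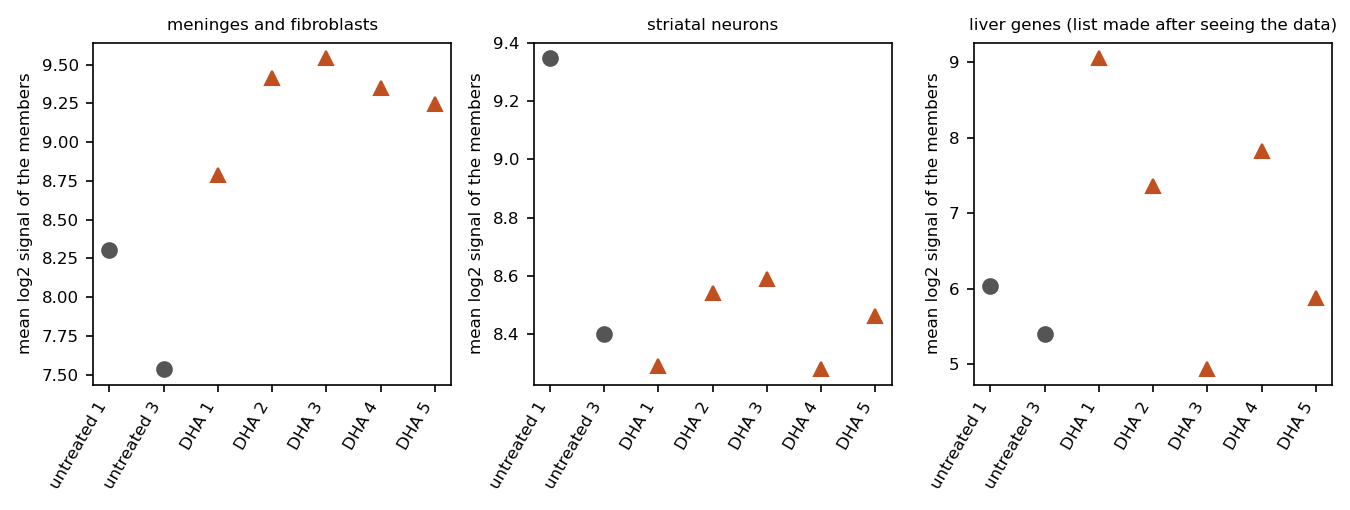
Mean log2 signal of the list members (vertical axes) in each of the 2 untreated arrays (circles) and 5 DHA arrays (triangles), for meninges and fibroblast genes, striatal neuron genes and liver genes. All 5 DHA arrays lie at 8.79 or above for the meninges list, untreated replicate 1 stands alone at 9.35 for the striatal list, and the liver genes range from 4.93 to 9.05 among the DHA arrays.

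Long-chain fatty acid synthesis and transport, the process nearest to the diet, did not pass as a list, with 19 of 31 members higher, a median of 0.06 and a camera adjusted p of 0.315. The stearoyl-CoA desaturase Scd1 differed by 0.34 (SE 0.10, limma adjusted p 0.345), with all 5 DHA arrays above both untreated arrays. The desaturases that make polyunsaturated fatty acids, Fads1 and Fads2, differed by 0.16 (SE 0.09) and 0.10 (SE 0.13). The elongase Elovl5 differed by 0.09 (SE 0.09), and Elovl2, detected in 0 of 2 untreated and 2 of 5 DHA arrays, is given no fold. Scd2 differed by 0.17 (SE 0.11), and Mfsd2a, the transporter that carries DHA across the blood-brain barrier, by 0.24 (SE 0.14). The brain fatty acid binding protein gene Fabp7 was detected in only 1 array and was not tested. The lists of PPAR targets and fatty acid oxidation (median -0.01, camera adjusted p 0.823) and of cholesterol synthesis and uptake (-0.01, adjusted p 0.847) did not pass.

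Hypothalamic neuropeptides did not pass camera as a list, with 12 of 26 members higher, a median of -0.03 and an adjusted p of 0.847, but passed the mixed test of fry in limma (adjusted p 0.00233). At an unadjusted limma p under 0.05, 2 of the 26 members were higher and 1 was lower, against 1565 of all 15284 probes. The mixed test compares the list with no other genes, so it does not set the neuropeptides apart. Of the feeding peptides, Pomc differed by -0.11 (SE 0.21), Cartpt by -0.06 (SE 0.17), Npy by 0.11 (SE 0.22), Hcrt by 0.16 (SE 0.15) and Pmch by -0.07 (SE 0.08). Oxytocin, Oxt, differed by 0.05 (SE 0.11) and vasopressin, Avp, by 0.08 (SE 0.14). When adjusted over the list alone, 1 member passed in each direction, and both are named after their values were seen. These were vasoactive intestinal peptide, Vip, a peptide of the suprachiasmatic nucleus (0.63, SE 0.12), and Tac2, the neurokinin B gene of arcuate neurons (-0.61, SE 0.11). The limma adjusted p of both over all probes was 0.168. The growth factor gene Bdnf differed by 0.38 (SE 0.18). The receptor genes Lepr and Insr were not tested, since they were detected in 0 and 1 of the 7 arrays. Feeding and energy balance receptors as a list had a median of -0.03 (camera adjusted p 0.823).

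The remaining lists did not pass camera either. Among cell types and regions, the medians and camera adjusted p were 0.04 and 0.604 for oligodendrocytes and myelin, 0.06 and 0.247 for their precursors, 0.03 and 0.247 for choroid plexus and ependyma, and -0.23 and 0.505 for erythrocytes. They were 0.16 and 0.116 for neurons of cortex, hippocampus and amygdala, -0.04 and 0.965 for thalamic neurons, -0.12 and 0.257 for markers of hypothalamic nuclei, and 0.58 and 0.35 for the pituitary. Among processes, they were 0.07 and 0.0683 for inflammatory signalling, 0.08 and 0.0952 for perineuronal net proteoglycans, 0.18 and 0.0952 for thyroid hormone, retinoid and tanycyte genes, and -0.04 and 0.116 for cytosolic ribosomal proteins. Immediate early genes had 0.06 and 0.165, monoamine genes -0.02 and 0.847, antioxidant genes -0.04 and 0.847, synaptic genes -0.02 and 0.897 and circadian clock genes -0.02 and 0.965. The direction of camera was upward despite a negative median for the PPAR, cholesterol, feeding receptor, antioxidant and circadian lists. The mean was positive while median and camera were negative for the synaptic and monoamine lists. The myelin gene Mbp differed by 0.18 (SE 0.13; other probes 0.01 and -0.08), the pituitary hormone gene Gh, detected in 1 of 2 untreated and 3 of 5 DHA arrays, by 0.63 (SE 0.59), and the globin gene Hba-a1 by -0.36 (SE 0.33). Prolactin, Prl, was detected in neither untreated array and in 2 of 5 DHA arrays, and was at least 1.01-fold higher.

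Transthyretin, Ttr, a product of choroid plexus and liver, differed by 1.18 (SE 1.05), with log2 signals from 7.34 to 11.59 among the DHA arrays. Liver transcripts such as Apoa2 and Ambp spread in the same way, with 6.74 to 11.48 and 4.97 to 10.86 among the DHA arrays (Ambp was undetected in 1 of them). A score of 27 such genes, chosen after their values were seen, was 6.03 and 5.39 in the untreated arrays and 9.05, 7.35, 4.93, 7.83 and 5.87 in the DHA replicates 1 to 5. Its difference between the diets was 1.30, with an exact two-sided permutation p of 0.381. With this score as a covariate, 0 probes passed in limma.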

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

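Of the tests in this part, those of a lower share of neuronal RNA, of a general loss of neuronal transcripts and of a rise of liver transcripts in every DHA animal were chosen only after the result was seen, and the liver pattern itself was noticed in the data.

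Among 112 values checked in the 5 DHA arrays, 8 had a single array far from the other 4 by the Dixon ratio (gap over range, critical value 0.71). Chance marks about 1 in 20 groups, or 5.6 here. DHA replicate 1 was the distant array for Fmod (ratio 0.863; 7.07 against 7.91 to 8.05), Avp (0.731; 13.05 against 13.38 to 13.50) and Lepr (0.774; 4.91 against 4.39 to 4.51, undetected in all arrays). DHA replicate 3 was the distant array for Npy (0.832; 11.04 against 11.70 to 11.83) and for the score of monoamine genes (0.717; 8.53 against 7.74 to 7.96). Ndufs6 stood apart in DHA replicate 2 (0.793; 13.61 against 13.50 to 13.53), Bgn in DHA replicate 4 (0.726; 8.02 against 8.23 to 8.30) and Insr in DHA replicate 5 (0.884; 5.33 against 4.48 to 4.58).

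Of the 21 splits of the 7 arrays into 2 and 5, only the real one gave as many probes at an unadjusted p under 0.05 in limma (1 of 21 splits, 1565 probes, highest other 1200). That share, 0.0476, met the rule of under 0.05 but is the smallest that 21 splits allow. The untreated pair also remained after the submitters left out 1 untreated sample as an outlier, so the splits are not on equal terms. Chance is therefore not excluded, and the count does not tell diet from anything else that parts the same arrays.

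Meninges and fibroblast genes were higher with DHA. A lower share of neuronal RNA would raise the other cell types alike. In these arrays, however, the meninges median lay 1.22 log2 above the highest of the microglia, oligodendrocyte, astrocyte and endothelium medians (bootstrap interval 0.91 to 1.37). The lowest meninges median over 4 other normalizations was 1.07. The bootstrap intervals in this part resample the genes of a list with the arrays held fixed. They do not measure the spread between animals. More meningeal tissue in the DHA dissections cannot be told apart from a response of meningeal cells. A separate list of meningeal transcripts had a median of 0.53 (33 genes, 6 of them also on other fixed lists; interval 0.41 to 0.74; above all 10000 random lists of like signal), between the 0.7 set for more tissue and the 0.3 set against it. Genes of random lists need not vary together as meningeal genes do, so this rank does not measure the spread between animals. The list score was 7.06 and 6.57 in the untreated arrays and 7.20 to 7.70 in the DHA arrays. More meningeal tissue and a response of meningeal cells both stay open, as does any difference in handling between the groups. The diet was tested no further.

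Striatal genes were lower with DHA, carried by untreated replicate 1, without which the median was 0.02. For less striatal tissue, a separate striatal list had a median of -0.10 (-0.0979; 29 genes, interval -0.28 to -0.02), between the bounds of -0.2 and -0.05 set for and against it, and also rested on untreated replicate 1 (score 8.76, against 8.43 in untreated replicate 3 and 8.39 to 8.52 in the DHA arrays). A general loss of neuronal transcripts would hold the other neuron lists within 0.2 of the striatal median. The lowest of the synapse, thalamus and cortex medians, that of thalamus, lay 0.43 above it, but its interval of 0.18 to 0.61 reaches under 0.2. Synapse lay 0.44 (0.25 to 0.62) and cortex 0.63 (0.38 to 0.83) above it. The cortex score, however, was high only in DHA replicates 2 and 5 (8.54 and 8.50, against 7.70 to 7.98 in the other arrays). The synapse score was highest in the same arrays (11.13 and 11.16, against 10.87 to 11.06), and both lists hold Slc17a7. The 2 lists are thus not independent and rest partly on 2 DHA arrays. The intervals cover the spread between genes and not between animals. The comparison therefore cannot decide on a general loss, and no conclusion is drawn from it. On the fixed list, untreated replicate 3 (score 8.40) lay within the range of the DHA arrays (8.28 to 8.59). The fall is thus a difference of 1 untreated array, not one shared by both. Less striatal tissue and an effect of the diet cannot be told apart on 2 untreated arrays that differ in this list, and neither is shown.

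Liver transcripts varied strongly between arrays, with a score at least 13.2-fold above the lowest array in DHA replicate 1; the lowest, DHA replicate 3, detected 4 of the 27 genes, and undetected genes were held at its lowest detected signal. The choroid plexus and ependyma list without Ttr had a median correlation with the score of 0.221 (9 genes, some of them ependymal). That lay under the 0.8 set as the bound for choroid plexus tissue. The interval of -0.18 to 0.63, taken over genes, is wide and leaves out the spread between animals. The low correlation thus argues against choroid plexus tissue in these arrays only. On a rise in every DHA animal, 1 DHA array, replicate 3, lay below both untreated arrays (4.93 against 6.03 and 5.39). DHA replicate 5 (5.87, with 20 of the 27 genes detected) lay between the 2 untreated arrays, and the other 3 DHA arrays lay above both. Replicate 3 is near the floor, and replicate 5 lay only slightly below untreated replicate 1. Both values were seen before the test was chosen, so no conclusion is drawn from them. Of 60 separate hepatocyte genes, 28 passed the filter. Their median correlation with the score was 0.926 (interval 0.85 to 0.95), and 0.827 without DHA replicates 1 and 4. Some passed only through arrays with a high score, which favours a high correlation. Bhmt, for example, was detected in 2 DHA arrays and in no untreated array. Of the members detected in all 7 arrays, Gnmt, Apoc1, Apoc3, Ass1 and Itih3 had 0.83 to 0.96, Cyp7b1 0.72, C8b 0.38 and Cyp27a1 0.34. Liver tissue or RNA carried into some samples stays a candidate source. Liver was dissected from the same mice per the series text, and the route was not tested.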

How the results depend on the processing

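In this part the exact permutation test of list scores, the lists without shared genes and the liver covariate were chosen only after the result was seen. The count of probes past an adjusted p of 0.05 in limma, 0 (1565 at an unadjusted p under 0.05), became 12 on the deposited values, 12 without background correction, 1 with normexp and an offset of 50, 52 with trend and robust variances and 10 at an adjusted p under 0.1, and 0 to 3 when 1 array was left out; without the detection filter 1215 probes were lower at an unadjusted p under 0.05, since more probes were tested. With an estimated correlation and with the directional test of fry, 0 lists passed; the exact permutation test also gave 0, but its 21 splits leave it too coarse to pass a list after adjustment unless nearly all do, so its values say nothing about stability. The 9 medians are by construction unchanged there: 1.41 for meninges (adjusted p 0.354, 0.105 and 0.218 in that order), 0.44 for matrix (0.354, 0.113, 0.218), 0.18 for endothelium (0.354, 0.13, 0.218), 0.19 for heat shock (0.429, 0.229, 0.381), -0.47 for striatal neurons (0.429, 0.3, 0.435), 0.35 for glucocorticoid-responsive genes (0.354, 0.13, 0.218), 0.37 for the immunoglobulin and histocompatibility list (0.429, 0.227, 0.381), -0.041 for oxidative phosphorylation (0.354, 0.105, 0.218) and 0.11 for astrocytes (0.354, 0.13, 0.218). The astrocyte median was 0.043 with median scaling (camera adjusted p 0.125). With the replicate number as a block, oxidative phosphorylation had -0.058 (camera adjusted p 0.0749), the thalamic list turned to 0.19 (camera adjusted p 0.00745), and limma called 0 probes (591 higher and 606 lower at an unadjusted p under 0.05). Deviations of samples with the same number had correlations of 0.00332 and 0.0338 (2 pairs). The 2 untreated arrays deviate from their mean by exact opposites, so these correlations are not independent. They cannot decide whether the numbers pair the samples. Only replicate numbers 1 and 3 occur in both groups, so the replicate block rests on few pairs. A block for slides was not run, because no slide is given. Leaving out 1 array gave medians of 0.048 to 0.15 for astrocytes, 0.090 to 0.29 for heat shock, 0.10 to 0.29 for endothelium, -0.83 to 0.021 for striatal neurons, 0.27 to 0.61 for the immunoglobulin list, 0.98 to 1.68 for meninges and 0.31 to 0.54 for matrix; a lone untreated array is assumed to vary like the others. The mean Bgn signal was 8.77 on the deposited values, 8.81 without background correction and 8.53 with an offset of 50, and the correlation between diets 0.992, 0.992 and 0.9903, where background compresses differences. For the other changes the cause was not tested. Over the 75 named probes, 15 of 1251 values under the alternatives had the other sign, in 9 probes, and 29 values passed. Of 505 values of uncalled lists, 485 kept direction and side of the threshold, 19 passed and 1 reversed. Low signal over background limits the dim probes most.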

Other observations

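The genes in this part were chosen only after their values were seen. A few marker genes of other brain regions and of the pituitary differed widely between single arrays of the same diet. The thyrotropin subunit Tshb of the pituitary had log2 signals of 4.40 and 6.81 in the untreated replicates 1 and 3 and 9.59, 6.80, 9.91, 4.71 and 4.70 in the DHA replicates 1 to 5. The shared hormone subunit Cga was 4.39 and 4.89, and 7.47, 4.77, 8.94, 4.47 and 4.68. The glutamate transporter Slc17a7, abundant in cortex, was 6.34 and 5.76, and 6.34, 9.64, 7.23, 6.10 and 9.98. The serotonin synthesis gene Tph2 of the raphe was 5.42 and 5.09, and 5.37, 5.48, 9.32, 6.32 and 5.73. The dopamine transporter Slc6a3 of midbrain neurons was 7.57 and 10.40, and 7.73, 7.56, 11.48, 9.51 and 9.81, and the striatal phosphoprotein Ppp1r1b was 11.39 and 9.51, and 9.51, 10.02, 10.11, 9.70 and 9.76. The lowest detected log2 signal lay between 5.08 and 5.23, depending on the array. The values of Tshb and Cga from 4.39 to 4.89 and the 5.09 of Tph2 were therefore undetected background.

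The circadian clock list did not pass camera (adjusted p 0.965), and neither of the following 2 members passed in limma. The activator Arntl differed by 0.39 (SE 0.11, limma adjusted p 0.338) and the repressor Ciart by -0.44 (SE 0.16, adjusted p 0.441) with DHA. For both genes all 5 DHA arrays lay on one side of the 2 untreated arrays. The granin Vgf differed by 0.23 (SE 0.10, adjusted p 0.482).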
